A study of Drosophila melanogaster with 3 samples.

How the data were processed

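Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on S2-DRSC cells, a male Drosophila melanogaster line derived from late embryos. The series comprises 3 libraries: 2 replicate libraries from an immunoprecipitation against the fly Myc protein and 1 library of input chromatin, the DNA taken before immunoprecipitation. The antibody is a rabbit polyclonal raised against residues 46 to 507 of Drosophila Myc, and cells were fixed with 1.8% formaldehyde for 15 minutes, per the labels' protocols. The protein is encoded by dm (diminutive), and binds DNA as a dimer with its partner Max.

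The values analysed here are a single peak list for the whole series. Base calls came from CASAVA 1.7.0.2 and 1.7.0.3, reads were aligned with BWA, and peaks were called with MACS2 on build BDGP5, per the submitters' processing notes, which give no version for BWA or MACS2 in the form used here. Coordinates are FlyBase release 5, per the file headers, and are given 1-based. Each peak carries a first base, a last base and a score that the authors deposited without saying which MACS statistic it is or on which log base. How the ChIP replicates and the input were combined, the peak threshold, and the treatment of duplicate and multiply mapping reads are not given in the sources used here. No peak or score is attributed to a single library, so the spread between replicates is unknown, the read depth of each library is not stated, and every test below measures the spread between peaks or between stretches of chromosome within 1 list. Scores were used to describe, rank and compare peaks within this list. In the closing observations they were also used to infer a background and read counts, under a hypothesis about what the score is.

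Before the data were examined, 11 tests, 30 alternative settings and 25 gene lists were fixed. Those concerning transcription start sites, gene lists, genomic features, E-box and other sequence motifs, and divergent promoters needed a genome or annotation of release 5. The gene table at hand belongs to release 6, whose positions were not transferred, so 8 tests were not run and no gene list was tested. The table was used only for gene names and for the order of neighbouring genes. The rule for named peaks was the 20 peaks with the highest score and the highest-scored peak of each chromosome arm or scaffold, given by position.

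Peaks were assigned to the 5 major arms (2L, 2R, 3L, 3R and X), chromosome 4, heterochromatin scaffolds (2LHet, 2RHet, 3LHet, 3RHet and YHet), the unplaced scaffold collections U and Uextra, and the mitochondrial genome. Arm lengths of release 5 were not used here, and the plan had been to give no densities without them. The densities below depart from that plan: after the data had been seen, the distance from the first to the last peak of each arm was put in place of its length. The peaks of each arm were compared with the arm's share of the summed distance by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 5 arms and exact (Clopper-Pearson) 95% intervals. These intervals cover counting error only and treat peaks as independent. Scores on X and on autosomal arms were compared by a two-sided permutation test of medians with 100000 resamples. The median distance between neighbouring peak midpoints was compared with 1000 random placements of the peaks between the first and last peak of the same arm. MACS summits were not used here, so midpoints stood in for them throughout.

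Further measures were added after the data had been seen. Peaks were counted in 1 Mb bins, leaving out the last, partly covered bin of each arm, and the ratio of variance to mean of these counts was compared with 1000 random placements. Runs of peaks were defined by midpoints no more than 15000 bp from the next. Scores on U and Uextra were compared with those on the major arms by the permutation test. In the longest run, periods from 1000 to 10000 bp were scanned for the strongest shared phase and set against 1000 random placements.

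Of the alternatives fixed in advance 3 were run: peaks scoring at or above the median of the list (arms), peaks within 1000 bp merged to 1 (arms) and a mean of log10 scores (X against autosomes). Those added after seeing the data were the list without the longest run, 1 Mb bins as the unit, placements within 1 Mb bins, bins of 0.5 Mb, X scores among peaks on a ladder of score values described in the closing observations, and the former settings applied to the added measures. The spacing of peaks merged within 1000 bp was also added then. The arm, score, spacing, dispersion, ladder and period procedures were tested on simulated data. With X peaks drawn at a lower rate than autosomal peaks, the arm test called X in 50 of 50 simulated lists of about 550 peaks. With equal rates it called X in 5 of 200 lists of about 660 peaks. Counts in both simulations were drawn independently for each arm. They do not show how the arm test behaves on peaks that lie in groups. The score permutation called 4 of 100 lists of 500 peaks with equal scores. In 40 lists of 200 uniformly placed peaks the spacing test called 1 and the dispersion test 2, and both called 40 of 40 lists of 200 peaks placed in groups. The ladder fit returned the simulated background of 30.0 from 1200 scores. The period scan returned 3994 bp for a simulated array of 48 peaks with a period of 4000 bp. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.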

Results

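Binding of Myc, a basic helix-loop-helix leucine zipper transcription factor that controls growth, was mapped across the genome of S2-DRSC cells. The data comprised 1 list of 1355 peaks from 2 ChIP replicates and 1 input library, which were not listed separately. Peaks lay on 14 sequences and covered 590500 bp. Their median width was 359 bp, with a range from 201 to 4597 bp, and 38 peaks had the shortest width. No 2 neighbouring peaks were separated by fewer than 50 bp. Peak scores, as given by the authors' peak caller, ran from 6.15 to 132.94 with a median of 13.15 and an interquartile range from 9.99 to 19.3.

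The first question was where in the genome the Myc peaks lay. The 5 major chromosome arms held 979 peaks, or 72.3% of the list. Arm 3R held 285 peaks, 2R held 223, 3L held 187, 2L held 173 and X held 111. Chromosome 4, the small dot chromosome, held 5 peaks, and the heterochromatin scaffolds, which carry the assembled part of the repeat-rich DNA near the centromeres and on the Y chromosome, held 29. The unplaced scaffold collections held 334 peaks, or 24.6% of the list, of which 281 lay on Uextra and 53 on U. The remaining 8 peaks lay on the mitochondrial genome.

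X carried fewer peaks for its length than the autosomal arms. Lengths were taken from the first to the last peak of each arm. A male line holds X in fewer copies than the autosomes, and these counts do not separate copy number from binding. X held 5.10 peaks per Mb, against 7.81 on 2L, 10.9 on 2R, 7.68 on 3L and 10.2 on 3R. Its share of the major-arm peaks was 0.607 times its share of the distance covered (95% interval 0.504 to 0.722, exact binomial test, adjusted p = 2.51e-09). By the same exact test, arms 2R (1.30 times, 1.15 to 1.46, adjusted p = 7.56e-05) and 3R (1.22 times, 1.10 to 1.34, adjusted p = 0.000339) held more than their share. The shares of 2L (0.929 times, 0.806 to 1.06, adjusted p = 0.309) and 3L (0.915 times, 0.799 to 1.04, adjusted p = 0.227) did not pass the exact test. These tests count each peak as independent, whereas peaks lay in groups along the arms, and no arm passed with 1 Mb bins as the unit. X then had a mean of 5.0 ± 5.66 peaks per bin (SD, n = 22 bins) and the autosomal arms 9.0 ± 8.89 (SD, n = 93 bins), with a permutation p of 0.045 before and 0.225 after adjustment over the 5 arms, against adjusted permutation p = 0.247 for 2R and 0.414 for 3R. Among peaks scoring at or above the median, 2R (1.01 times, adjusted exact p = 0.947) and 3R (1.13 times, 0.287) did not pass either, and without its longest run of peaks 2L held 0.750 times its share (adjusted exact p = 0.000189).

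Over all peaks, those on X did not differ detectably in score from those on the autosomes. The median score was 12.3 for the 111 X peaks and 11.9 for the 868 autosomal peaks, a difference of 0.40 (two-sided permutation test, p = 0.638). Among peaks whose score lay within 0.015 of a ladder of recurring score values, a subset chosen after seeing the data, the medians were 12.7 on X (n = 57) and 11.1 on the autosomes (n = 346), a difference of 1.60 (two-sided permutation test, p = 0.0177). Both tests treat each peak as independent, whereas 15 of these 57 X peaks lay in the bin from 1 to 2 Mb. Among single arms, 2L had the highest median score, 13.4, and 2R the lowest, 11.1. The 5 peaks on chromosome 4 had a median score of 25.6.

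**Figure D1:**
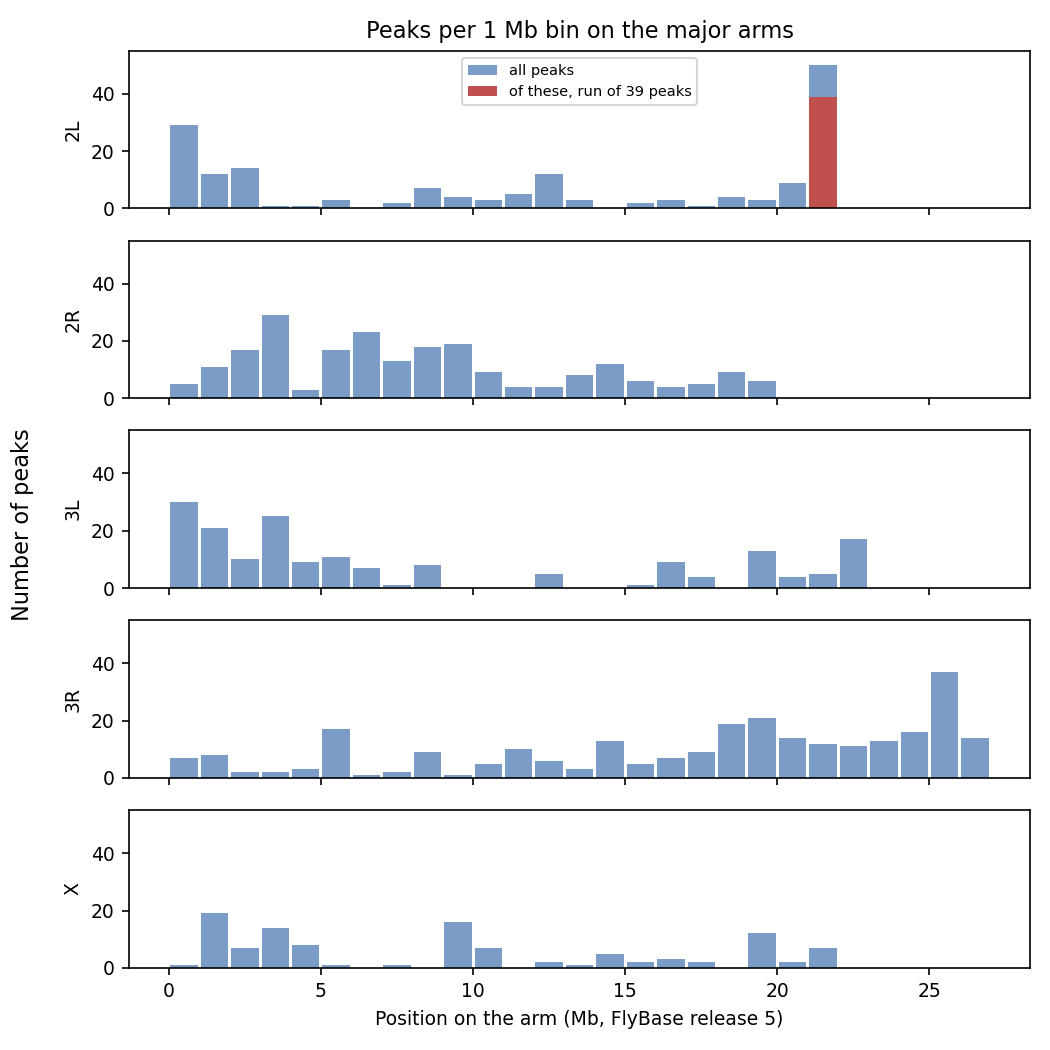
Number of Myc peaks (vertical axis) in each 1 Mb bin along the 5 major arms (horizontal axis, Mb, FlyBase release 5), 1 panel per arm, with the run of 39 peaks on 2L in red. Bars start at 0 and the last, partly covered bin of each arm is left out. Counts range from 0 in 13 bins to 50 in the bin that holds the run.

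Within arms the peaks were concentrated in particular stretches. Over 115 bins of 1 Mb the count per bin had a median of 6, a maximum of 50 and a ratio of variance to mean of 8.76, whereas 1000 random placements gave a median ratio of 1.48 and a highest of 2.00 (permutation of positions, p = 0.001, the smallest that 1000 placements can give). The 3 Mb at the distal end of 2L held 55 peaks, or 18.3 per Mb, and the following 5 Mb held 7, or 1.40 per Mb. On 3L, the first 6 Mb held 106 peaks and the 7 Mb from 9 to 16 Mb held 6. On 3R, the stretch from 18 to 27 Mb held 157 peaks, or 17.4 per Mb, and the first 5 Mb held 22, or 4.40 per Mb. On X, the stretch from 1 to 5 Mb held 48 peaks and that from 5 to 9 Mb held 2. On 2R, the stretch from 5 to 10 Mb held 90 peaks, or 18 per Mb, and that from 11 to 20 Mb held 58, or 6.44 per Mb. These stretches were chosen after their counts had been seen.

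At a finer scale, neighbouring peaks lay closer together than placed at random. The median distance between neighbouring midpoints on the major arms was 26422 bp, against 79054 bp in random placements (95% of placements between 73853 and 84570 bp, permutation of positions, p = 0.001, the smallest that 1000 placements can give). When each peak was placed at random within its own 1 Mb bin, the placed median fell to 51888 bp, and the observed distance lay below it (permutation of positions, p = 0.001). With peaks within 1000 bp merged to 1, the observed and placed medians were 34521 and 88807 bp (permutation of positions, p = 0.001). The placements were uniform and made no allowance for gene density, for repeated sequence or for sequence to which reads cannot be mapped. Pairs of neighbouring peaks with a similar distance between them recurred at separate places on 2L, 2R, 3L and 3R. They lay more than 1000 bp apart, so merging kept them, and placement within bins did not leave them out either. Their part in the closer spacing, and whether they lie in repeated sequence, was not tested. By arm, the median distance was 7836 bp on 2L, 26658 bp on 2R, 28345 bp on 3L, 33229 bp on 3R and 31831 bp on X. Without its longest run, 2L had a median distance of 22921 bp.

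The longest run of neighbouring peaks lay on 2L, from base 21418367 to base 21541295. It held 39 peaks in 122929 bp and made up most of the 50 peaks in the bin from 21 to 22 Mb. Its peaks had a median width of 530 bp and a median score of 14.2. They recurred at a period of 5008 bp, the strongest of the periods scanned, with a phase concentration of 0.577 on a scale from 0 to 1, against a median of 0.387 for the best period of random placements (permutation of positions, p = 0.003). The highest peak of the run, which was also the highest on 2L, spanned bases 21513198 to 21513967 with a score of 45.66. On the major arms 4 other runs held 8 or more peaks. They lay on 3R from base 25548926 to base 25632940 with 16 peaks, on 2R from base 9844771 to base 9896295 with 11 peaks, on 3L from base 626154 to base 654859 with 9 peaks and on X from base 3994941 to base 4012125 with 8 peaks.

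**Figure D2:**
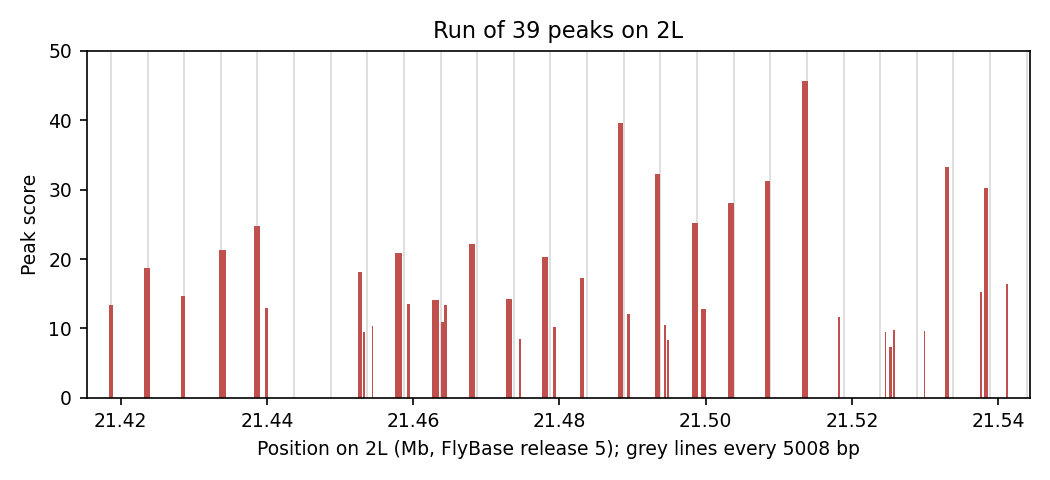
The run of 39 peaks on 2L, with position in Mb (FlyBase release 5) on the horizontal axis and peak score on the vertical axis; each red bar is 1 peak drawn at its true width. Grey lines are spaced every 5008 bp, and the highest bar has a score of 45.66.

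The highest-scored peaks lay outside the major arms. Of the 20 peaks with the highest score, 7 lay on U, 6 on the mitochondrial genome, 5 on Uextra, 1 on a heterochromatin scaffold and 1 on a major arm. The highest of all lay on U at bases 5288478 to 5289656, with a score of 132.94. The highest on Uextra lay at bases 25090372 to 25090965, with a score of 122.55. The major-arm peak among the 20 lay on 2R at bases 943247 to 943675, with a score of 92.21. The highest peak of 3L was at bases 24457228 to 24458119 with a score of 61.0, that of X at bases 14937689 to 14938412 with 53.39, that of 3R at bases 27283623 to 27284375 with 43.83, and that of chromosome 4 at bases 1316243 to 1316921 with 29.16. The highest peak on a heterochromatin scaffold was on 3RHet at bases 1523746 to 1524918 with a score of 61.66. Those of 3LHet (bases 1285242 to 1286069, 43.72), YHet (bases 72354 to 73277, 33.79), 2RHet (bases 2093023 to 2094179, 30.12) and 2LHet (bases 124248 to 124726, 12.80) were lower.

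Peaks on the unplaced scaffolds scored higher as a group. The median score was 19.7 for the 334 peaks on U and Uextra and 11.9 for the 979 peaks on the major arms, a difference of 7.74 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Their median width was 376 bp, against 353 bp on the major arms. The heterochromatin scaffolds had a median score of 15.5. The permutation test treats each peak as independent. How multiply mapping reads were treated is not known, so the higher scores on U and Uextra cannot be read as stronger Myc binding.

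**Figure D3:**
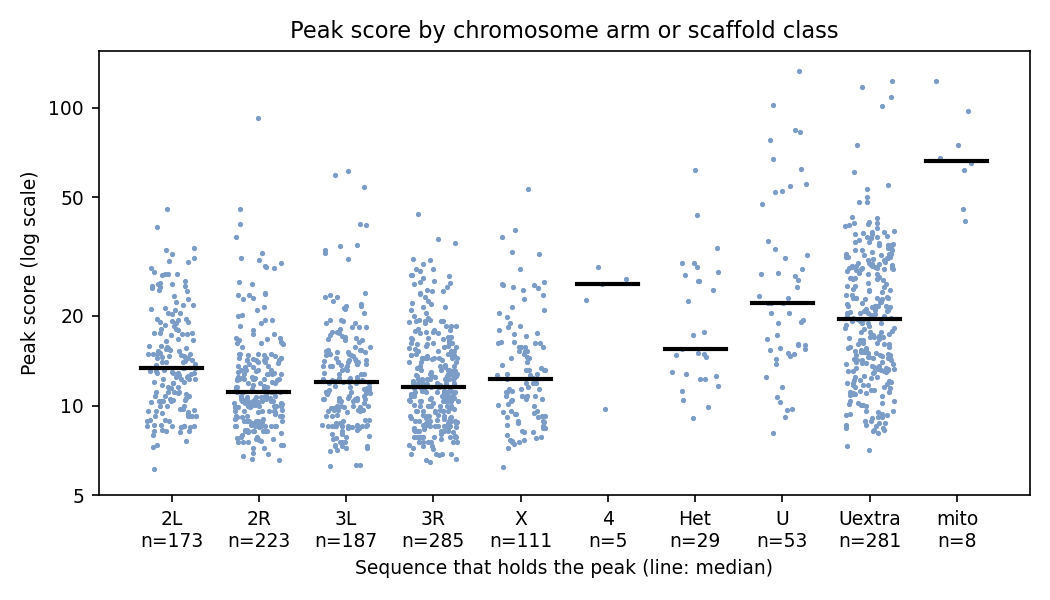
Peak scores (vertical axis, log scale) by the sequence that holds the peak (horizontal axis), where Het stands for the heterochromatin scaffolds and mito for the mitochondrial genome; each point is 1 peak and each black line a median. Medians lie between 11.1 and 13.4 on the 5 major arms, at 22.0 on U, at 19.5 on Uextra and at 66.2 on the mitochondrial genome.

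The mitochondrial genome was covered almost throughout between its first and last peak, and no peak lay beyond base 14922. Its 8 peaks spanned bases 13 to 14922 and covered 90.4% of the 14910 bp between them. They had a median width of 1283 bp, against 353 bp on the major arms, and a median score of 66.2. The highest, at bases 13 to 1149, had a score of 123.02. A run of 7 peaks on U had the same form. It spanned 14963 bp, from base 5288478 to base 5303440, was covered to 86.4%, and had a median score of 77.8. Together these 15 peaks held 11 of the 20 highest scores in the list. Whether they reflect Myc binding was not tested.

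**Figure D4:**
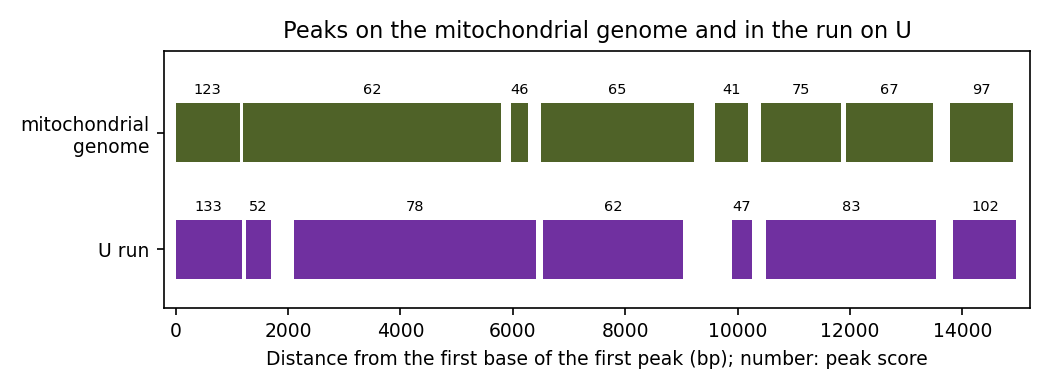
Peaks on the mitochondrial genome (upper row, green) and in the run of 7 peaks on U (lower row, purple), drawn to scale by distance in bp from the first base of the first peak in each; the number above each block is its score, rounded. Both rows extend over about 15 kb, with the highest scores of each, 123.02 and 132.94, at the left end.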

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

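Of 32 alternatives to 9 results, 24 kept the direction and the side of the 0.05 threshold, 5 lost the call, 2 gained one and 1 changed direction. Among peaks scoring at or above the median, the ratio of 2L turned from 0.929 to 1.20 (adjusted exact p = 0.153, neither called), and those of 2R (1.01) and 3R (1.13) lost their call, while X kept its call. Fewer peaks were tested, and the arms also kept unequal parts of their peaks. Kept were 89 of 173 peaks on 2L, 69 of 223 on 2R and 105 of 285 on 3R. The longest run on 2L was kept for the most part, with a median score of 14.2 against 13.15 for the list. This setting was not run without it. With 1 Mb bins as the unit, X (0.607), 2R (1.35) and 3R (1.20) kept their direction and lost their call, because bins vary more than counting error allows. Without the longest run, 2L fell to 0.750 and was called (adjusted exact p = 0.000189; up to 0.722 over the alternatives for 2L). Among the peaks on the background ladder described under the other observations, X scored 1.60 above the autosomes (permutation p = 0.0177), where the difference over all peaks was 0.40. That permutation test treats peaks as independent, and the cause was not tested. The closer spacing, the uneven density and the higher scores of U and Uextra kept their call in every alternative run. The bin, run, ladder and placement alternatives, the spacing of merged peaks, and those on uneven density and on U and Uextra, were chosen after seeing the data. Of 30 alternatives fixed in advance, 3 were run; the rest concern start sites, gene lists, features, motifs and promoters, for which no release 5 genome was used here. No paired analysis was possible because the list carries no replicate. Read depth, replicate spread and arm lengths are unknown here, which limits every comparison of densities.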

Other observations

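All tests in this part were chosen after the values they bear on had been seen, and each explanation is a hypothesis.

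The score column is unnamed, and 805 different values served 1355 peaks. A candidate explanation is that it is −log10 of a Poisson p-value, which for whole read counts over 1 fixed background can take only a ladder of values. With the best background, 32.31 reads, 390 scores lay within 0.01 of the ladder, against a median of 108 and a maximum of 119 in 100 lists with jittered scores. Each score was jittered separately by up to 0.2, which also breaks up repeated values. The comparison therefore does not separate a Poisson ladder from another source of repeated values. The tolerance was then widened to 0.015, after a frequent score had fallen just outside, which put 436 scores (32.2%) on the ladder, where 7.25% of the score axis between 8 and 20 lies that close to it. All 19 score values shared by 10 or more peaks then lay on the ladder, though its background had been fitted to the same list. If this reading holds, peaks on the ladder were scored against a genome-wide background and had a median of 78 reads, 2.41 times that background, and peaks off it were scored against a higher local one. On the ladder were 41.2% of major-arm peaks, 9.28% of U and Uextra peaks (31 of 334, Fisher's exact p = 1.74e-30) and 0 of 29 on the heterochromatin scaffolds.

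The mitochondrial genome and the run of 7 peaks on U held some of the highest scores, and the form of both may come from sequence they share. Bases that no peak covered coincided over 890 bp, against a median of 249 bp and a maximum of 1072 bp when the order of peaks and gaps on U was shuffled 10000 times (permutation p = 0.00090), and over 273 bp with the run reversed. This goes with a copy of mitochondrial DNA in U whose reads are split between both places, though no sequence was compared. Whether mitochondrial DNA made up a larger part of the ChIP than of the input library was not tested. No biological explanation was tested.

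The run of 39 peaks on 2L may be a tandem repeat, since its period of 5008 bp was stronger than in nearly all of 1000 random placements (permutation of positions, p = 0.0030). The run spans 24.5 periods, a length and not a count of copies. In the gene table of Release 6, 23 His1 copies lie in a row on 2L, a ratio of 1.07. For the other histone genes it lists 20 copies in a row of His2A, 23 of His2B, 22 of His3 and 22 of His4. The histone gene cluster is therefore a candidate source, identified by arm and copy number and not by position. Whether the copies differ in binding, or share reads that mapping spread over them, cannot be told apart. A main peak was taken for each copy within a window of the repeat, and it need not be the highest peak of the copy. Scores of the main peak varied 3.91 times over 21 copies. Under a first definition with a wider window, replaced after its value had been seen, they varied 4.80 times over 23. Simulated even sharing reached 3.91 in 1.3% of 1000 lists (median 2.41), but neither ratio decides, because the simulation assumed the genome-wide background, on whose ladder only 3 of the 39 peaks lay, and copies with no such peak are left out, including 2 with no peak at all.

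The uneven density along the arms does not come from the 2L run alone: without it the ratio of variance to mean was 7.19, above the highest of the placements, 2.14. Gains of copy number in this cell line could raise both the input and the peak density, and denser bins did have a smaller share of peaks on the ladder (66 bins with 5 or more peaks, Spearman's rho = -0.277, permutation p = 0.025; Pearson's r = -0.314, p = 0.0099). Without the 2 bins farthest from the median count, rho was -0.237 (permutation p = 0.0601) and r -0.257 (p = 0.0405), without the 2L run they were -0.240 (p = 0.0525) and -0.258 (p = 0.0359), and within arms rho passed only on 3R (-0.698, 20 bins, permutation p adjusted over 5 arms = 0.0048). Of X, which a male line holds in fewer copies than autosomes, 51.4% of peaks lay on the ladder against 39.9% on autosomal arms (Fisher's exact p = 0.0241, or 0.052 without the 2L run); 15 of the 57 lay in the bin from 1 to 2 Mb, and 3R had 47.7%. With bins as the unit the X difference did not pass (permutation p = 0.143), and with rules made stricter after the first p-values had been seen, copy number and clustered binding cannot be told apart. Repeated sequence elsewhere on the arms was not examined, so its part in the closer spacing, the uneven density and the ladder shares is unknown.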
